A study of Mus musculus with 6 samples.

How the data were processed

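Total RNA from cultured adipose-derived mesenchymal stem cells of C57BL/6 mice was labelled with biotin and hybridised to Illumina single-colour bead arrays, 1 array at each of days 0, 1, 3, 6, 10 and 14 of osteogenic medium. The files deposited by the authors hold a linear signal intensity per probe and array that was not normalized between arrays, and per the file headers a detection p-value for each probe and array. The detection p-value is read here as the share of negative control signals above the probe signal. A further table deposited by the authors gives another unit, a signed fold of each later array over the control, in which a fall is written as minus the inverse ratio. The scaling behind that fold table, the scanner software and any background subtraction are not given in the sources used here. The deposited series matrix holds the same intensity values for part of the probes.

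The signal columns are named C and T1 to T5. They were taken as day 0 and days 1, 3, 6, 10 and 14 in that order, and this was checked against the series matrix: on each of the 6 arrays 17785 of 17785 compared values were equal within a tolerance of 1e-05. The table has 46649 entries. The 6 without a probe identifier and the 30 with a repeated identifier were left out, which leaves 46613 probes. Signals were background corrected with the nec method of limma 3.58.1 (R 4.3.3), which uses the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale. Detected means a detection p under 0.01, and 15504 probes were detected on at least 1 array. By array, from day 0 to day 14, the detected probes numbered 12891, 13041, 13216, 13140, 13248 and 13980, and the highest signals lay between 62522 and 66712. Signal over background and the number of arrays limit the precision. Bead standard errors are not given in the files used here, so no error within an array was computed.

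Gene symbols came from a table of the probes in the series matrix, and 13807 probes had a single symbol. Their symbols were compared with a reference gene table by gene identifier, where 13790 were found and 0 symbols changed. No genome build is given for the array, so no coordinates are reported. A gene was represented by its probe with the highest mean over the 6 arrays, and 3034 genes had more than 1 probe. Of 9751 genes, 8881 had their representing probe detected on at least 1 array and were tested, and 7064 were detected on all 6. Other detected probes of the named genes were compared: 57 such probes, 50 of them for genes with a call, had 0 slopes of the opposite sign among the genes with a call.

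The trend of each gene was tested with limma (lmFit, then eBayes with an intensity trend) as a two-sided test of the slope on log2(day + 1), with 4 residual degrees of freedom and Benjamini-Hochberg adjustment over all tested genes at 0.05. Departures from a straight line count as error in this test. Comparisons between single days have no replicates and therefore no test. They count genes at least 2-fold apart among those detected on either array. The comparisons with day 0 share the day 0 array, so the overlap between them is not reported. A fold is given as at least N-fold when the gene was detected on only 1 of both arrays, using the lowest detected level on the other array. Such a bound is computed on the normalized scale and need not hold on another scale. Named genes at 50% or more of the highest signal on an array were listed after their values were seen: Actb, Actg2, Adm, Apod, B2m, Ccn2, Cdkn1c, Col1a1, Gapdh, Hp, Igfbp3, Lpl, Mgp, Serpina3n, Serping1 and Timp3. The size of their folds and slopes is not resolved. The 29 gene lists were tested along the trend with camera from limma at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 28 lists that had at least 3 measured members. Each list call was repeated with an estimated correlation, under which 0 of the 13 calls held, and with fry. With an estimated correlation camera also tests on the 4 residual degrees of freedom, not on a number set by the genes. The endoplasmic reticulum stress and amino acid response list lost its call there at an estimated correlation of 0.074. A call lost in that setting therefore does not by itself show that members moved together. At single days the median of a list is described with its place among 10000 random lists of the same size matched on expression in 20 bins. Of 647 list symbols 424 were tested.

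The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 steepest rises and falls among called genes detected on all 6 arrays, the 10 highest and lowest genes on day 14 and the 5 highest and lowest on the other days among genes detected on both arrays. It further takes the 5 largest bounds in each direction between day 0 and day 14, the 3 highest and lowest genes of each successive step, the 4 members of each list with the largest slopes, and genes of the osteoblast, adipocyte and reference programmes named in advance. Predicted loci were not named. Dcn, Fasn and Dgat2, which moved against the other members of their lists, fall outside this rule and were chosen after their values were seen. Sox4, Runx2, Bglap, Ibsp, Spp1, Dmp1 and Mki67 were on the list of genes to name and were not analysed here, because no probe of the gene table used carries their symbol. That table covers only the 17788 probes of the series matrix. All 17785 of these that were compared had a detection p under 0.05 on at least 1 array. Whether genes and list members without a symbol were undetected or only unnamed cannot be told.

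The alternatives were quantile normalization without background correction, median scaling, the signals as deposited, an offset of 50, no detection filter, detection on all 6 arrays, the mean of all probes of a gene, the day itself or its rank as time scale, a quadratic term, other eBayes settings, the later days as 1 group, each time point left out in turn, thresholds of 1.5-fold and 3-fold, and the authors' fold table. The trend test was run on simulated data with the same number of arrays, in which 200 of 8881 genes were given a slope: 5.97% of those with a slope of 0.25 were recovered, 58.2% with 0.5 and 80.3% with 1, and 4 unchanged genes were called. The list test called the list of changed genes and 0 of 28 random lists. Simulated genes varied independently, whereas the estimated correlation in the data reached 0.889 for the interferon response genes. The simulation therefore cannot show how the list test behaves when members move together, or how many unchanged genes would be called in such data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.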

Results

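Gene expression was measured in mesenchymal stem cells isolated from the dorsal and inguinal fat of C57BL/6 mice and turned towards bone-forming cells in culture. The osteogenic medium held ascorbic acid, β-glycerophosphate and dexamethasone, a synthetic glucocorticoid. RNA was taken at day 0, before the medium acted, and after 1, 3, 6, 10 and 14 days. Each of the 6 time points has 1 Illumina bead array and no replicate, and no later array comes from cells kept without the medium, so days in the medium and days in culture run together. Between 12891 (day 0) and 13980 (day 14) of 46613 probes were detected per array, and the median signal ran from 126.8 on day 6 to 141.3 on day 1. The tested set held 8881 genes with a detected probe on at least 1 array. Slopes are in log2 units per unit of log2(day + 1), given ± SE from the limma fit over the 6 arrays, and the number of arrays limits the precision of every value.

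Sox11, the transcription factor named in the title of the series as an inhibitor of osteoblast differentiation, fell over the course. On its brightest probe, ILMN_1235647, the normalized log2 level was 11.67 on day 0, 11.23 on day 1, 8.75 on day 3, 7.94 on day 6, 7.01 on day 10 and 6.54 on day 14. Sox11 was 1.36-fold lower than day 0 on day 1, 7.58-fold lower on day 3, 13.3-fold lower on day 6 and 25.3-fold lower on day 10. By day 14 its signal was no longer well above background, with a share of 0.0125 of negative control signals above it. On the normalized scale Sox11 was therefore at least 32.7-fold lower than on day 0. The other probes of Sox11 had the same direction: ILMN_2616196 went from 10.16 to 6.10 and ILMN_2740231 from 9.22 to 5.22 between day 0 and day 14, and the latter was detected on 2 arrays. The slope of Sox11 was -1.42 ± 0.109 (limma adjusted p = 0.00189), and it passed without each single time point, with the highest adjusted p of 0.0150 when day 10 was left out. In the fold table deposited by the authors, Sox11 was 1.35-fold lower on day 1, 6.32-fold lower on day 3 and 17.31-fold lower on day 14. The bound of 32.7-fold thus does not hold on that scale.

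**Figure D1:**
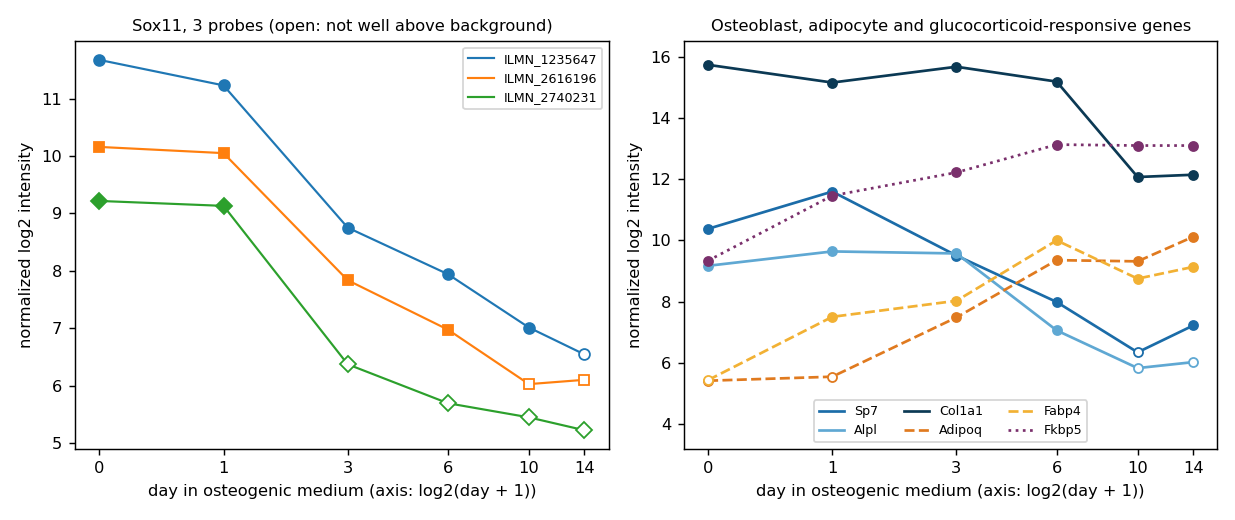
Normalized log2 intensity by day in osteogenic medium, 1 array per point, on an axis spaced as log2(day + 1). The left panel shows the 3 probes of Sox11 and the right panel Sp7, Alpl, Col1a1, Adipoq, Fabp4 and Fkbp5; open symbols mark levels not well above background. Sox11 on its brightest probe goes from 11.67 to 6.54.

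The time trend asks which genes rose or fell over the course, as a slope fitted through the 6 arrays. A call does not mean a steady change: Chac1 went from 12.46 on day 0 to 8.60 on day 1 and 7.36 on day 14. Apod, which codes for the lipid-binding apolipoprotein D, had the steepest rise among genes detected on all 6 arrays, at 2.39 ± 0.357 (adjusted p = 0.00582). It was followed by Cdkn1c, a cyclin-dependent kinase inhibitor, at 1.93 ± 0.211 (adjusted p = 0.00343), and Hp, the haemoglobin-binding plasma protein haptoglobin, at 1.84 ± 0.232 (adjusted p = 0.00433; 2.30 ± 0.215 on a second probe). Igfbp3, an insulin-like growth factor binding protein, rose by 1.73 ± 0.222, Itgbl1 by 1.66 ± 0.158, Selenbp1 by 1.64 ± 0.169, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 1.60 ± 0.138. Selenop, a selenium carrier, Ifi205, Ramp2, Ndrg2 and Ramp1 completed the 12 steepest rises, with slopes from 1.57 for Selenop to 1.34 for Ramp1. Apod, Cdkn1c, Hp and Igfbp3 lay at 50% or more of the highest signal on days 10 and 14, so the size and order of their slopes are not resolved. Uhrf1, needed to maintain DNA methylation through replication, had the steepest fall among genes detected on all 6 arrays, at -1.72 ± 0.285 (adjusted p = 0.00712). The mitotic kinase Plk1 fell at -1.64 ± 0.277, the chemokine Cxcl14 at -1.55 ± 0.112, the spindle protein Prc1 at -1.54 ± 0.245 and the replication helicase subunit Mcm5 at -1.46 ± 0.25. Cdca8, Cenpa, Specc1, Mthfd1l, Slc7a5, Slc20a1 and Chac1 followed, from -1.40 for Cdca8 to -1.14 for Chac1. Over all 8881 genes, 1648 rose, 1572 fell and 5661 did not pass at an adjusted p of 0.05, so 36.3% were called and 51.2% of these rose. The count rests on the last arrays: without day 14 it was 590 risen and 432 fallen, and without day 10 it was 770 and 639. Ramp1 and Cenpa lost their calls without day 14 (adjusted p = 0.0559 and 0.0586), and a test of a linear and a quadratic term together gave 973 risen and 859 fallen.

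Genes of the osteoblast programme went both ways. Sp7, the transcription factor osterix that commits cells to the osteoblast lineage, was 2.32-fold higher on day 1 than on day 0, then lower, and fell over the course at -1.18 ± 0.236 (adjusted p = 0.0115). Alpl, the alkaline phosphatase used as an osteoblast marker, fell at -1.03 ± 0.231 (adjusted p = 0.0160), and Col1a1, the main collagen chain of bone matrix, fell at -0.93 ± 0.259 (adjusted p = 0.0304). The log2 level of Alpl was 9.17 on day 0, 9.64 on day 1 and 9.58 on day 3. Alpl was not detected on days 10 and 14, so background limits its slope. Col1a1 stood at 15.7 on days 0 and 3, at 15.2 on day 6 and at 12.1 on day 10. Omd, a keratan sulfate proteoglycan of mineralised matrix, rose at 1.51 ± 0.228, Mgp, an inhibitor of calcification, at 1.33 ± 0.166, and the sphingomyelinase Smpd3 at 1.13 ± 0.232, while the phosphate transporter Slc20a1 fell at -1.16 ± 0.133. Of 14 measured osteoblast and mineralised matrix genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.956; its mean slope was 0.01, its median slope -0.02). Among 9 measured osteoblast transcription factors, 2 rose, Maf at 0.45 ± 0.135 and Zfp521 at 0.40 ± 0.127, and 4 fell, Dlx5 among them at -0.32 ± 0.0838 (3 and 4 adjusted over the list alone; camera adjusted p = 0.408). The call of Alpl ended without day 10 or day 14 (adjusted p up to 0.0717), that of Col1a1 without day 1, 10 or 14 (up to 0.136), and that of Smpd3 without day 0 (0.0722). Maf lost its call without any 1 of days 1, 6, 10 and 14 (up to 0.115), Zfp521 without any 1 of days 3, 6, 10 and 14 (up to 0.129), and Dlx5 without any 1 of days 0, 6, 10 and 14 (up to 0.126). Dlx5 was detected on only 2 of the 6 arrays, with its highest log2 level at 7.44, so background limits its slope.

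Adipocyte genes went both ways, with more risen than fallen. Plin4, a coat protein of lipid droplets, rose at 2.25 ± 0.262 (adjusted p = 0.00364), the adipokine gene Adipoq at 1.32 ± 0.140 (adjusted p = 0.00341), Klf15 at 1.11 ± 0.138 and Car3 at 0.99 ± 0.192. Fabp4, a fatty acid carrier, rose at 0.92 ± 0.201, the lipase gene Lpl at 0.65 ± 0.0988, and the adipogenic transcription factors Cebpa and Pparg at 0.65 ± 0.0747 and 0.44 ± 0.0859. The fatty acid synthase gene Fasn and the triglyceride-forming Dgat2 fell, at -0.50 ± 0.119 and -0.36 ± 0.0790. Of 19 measured members, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with camera adjusted p = 0.0123, and adjusted p = 0.601 with an estimated correlation. Among genes detected on all 6 arrays the list did not pass (camera adjusted p = 0.366). That filter drops the risers Plin4 and Adipoq, each detected on 4 arrays, Fabp4 on 5 and Car3 on 3, so it cannot judge their rise. Background limits the slope of Car3. Fabp4 lost its call without day 0 (0.0984), Car3 without day 14 (0.0571), and Pparg without day 0 or day 14 (up to 0.0551), Fasn without day 10 or day 14 (up to 0.0695) and Dgat2 without day 0 or day 10 (up to 0.0827). Of 6 measured chondrocyte genes, Sox5, a cartilage transcription factor, rose at 0.93 ± 0.0762 and Comp at 0.98 ± 0.180, and Sox6 fell at -0.38 ± 0.0874 (2 risen and 1 fallen, 2 and 2 adjusted over the list alone; camera adjusted p = 0.722). Sox9, the master regulator of cartilage formation, did not pass at 0.24 ± 0.109 (adjusted p = 0.124). Without day 14 the calls of Comp (0.0543) and Sox6 (0.0841) ended, and Sox6 also lost its call without day 10.

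Glucocorticoid-responsive genes with a call all rose. Sult1a1, a sulfotransferase, had a slope of 2.56 ± 0.204 (adjusted p = 0.00189), the iron-carrier-binding lipocalin Lcn2 of 2.49 ± 0.269 (adjusted p = 0.00343), Cdkn1c of 1.93 ± 0.211 and glutamine synthetase, Glul, of 1.62 ± 0.103 (adjusted p = 0.00189). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose at 0.93 ± 0.139 and stood 4.35-fold above day 0 on day 1 and 13.5-fold above on day 14. Of 22 measured members, 15 rose and 0 fell (19 and 0 adjusted over the list alone), with camera adjusted p = 2.3e-09, and adjusted p = 0.601 with an estimated correlation. Among complement genes, Cfb, a factor of the alternative pathway, rose at 1.45 ± 0.213, C2 at 1.32 ± 0.204, C1s1 at 1.15 ± 0.180 and the complement inhibitor gene Serping1 at 1.06 ± 0.166. Of 7 measured complement genes 6 rose and 0 fell, also adjusted over the list alone, with camera adjusted p = 0.00252, and adjusted p = 0.601 with an estimated correlation. Interferon response genes had 8 risen and 0 fallen of 16 (10 and 0 adjusted over the list alone), with camera adjusted p = 0.00052, and adjusted p = 0.601 with an estimated correlation. Gbp3, a guanylate-binding protein, rose at 1.01 ± 0.268, the immunoproteasome subunit Psmb9 at 0.95 ± 0.212, Igtp at 0.87 ± 0.238 and Oas2 at 0.79 ± 0.194. Each of these 4 lost its call without day 14 or without day 0 (adjusted p up to 0.0721, 0.0740, 0.0803 and 0.0671), and Gbp3 and Igtp also without day 6 or day 10.

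Lysosome and autophagy genes had 8 risen and 0 fallen of 19 measured (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00429, and adjusted p = 0.601 with an estimated correlation. The lysosomal protease Ctsa rose at 0.81 ± 0.209, and Gabarapl1 and Map1lc3b, which code for autophagosome proteins, rose at 0.64 ± 0.131 and 0.53 ± 0.0854. Without day 14 Ctsa (adjusted p = 0.0913) and Gabarapl1 (0.0518) lost their calls, and Ctsa also without day 10. Fry, which tests whether members move 1 way on balance without comparing them with other genes, did not call the lysosome and autophagy list (adjusted p = 0.0980) or the interferon response list (0.0965).

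Cell cycle genes with a call all fell. Birc5, the mitotic protein survivin, fell at -1.82 ± 0.327 (adjusted p = 0.00869), the nucleotide salvage enzyme Tk1 at -1.77 ± 0.352, the mitotic kinase Aurka at -1.68 ± 0.299 and Cdc20, an activator of the anaphase-promoting complex, at -1.65 ± 0.297. Of 27 measured members, 22 fell and 0 rose (25 and 0 adjusted over the list alone), with camera adjusted p = 1.7e-09, and adjusted p = 0.601 with an estimated correlation. Endoplasmic reticulum stress and amino acid response genes had 14 fallen and 0 risen of 22 (15 and 0 adjusted over the list alone), with camera adjusted p = 5.9e-06, and adjusted p = 0.601 with an estimated correlation. The amino acid transporter gene Slc7a5 fell at -1.16 ± 0.0924, Chac1, which degrades glutathione, at -1.14 ± 0.232, and the serine synthesis enzymes Phgdh and Psat1 at -0.82 ± 0.0956 and -0.80 ± 0.0890. Cholesterol biosynthesis genes had 10 fallen and 0 risen of 17 (11 and 0 adjusted over the list alone), with camera adjusted p = 1.3e-04, and adjusted p = 0.601 with an estimated correlation. Lss fell at -0.95 ± 0.195, Cyp51 at -0.90 ± 0.154 and Fdps at -0.85 ± 0.217, all enzymes of sterol synthesis. Tk1 lost its call without day 14 (0.0556), Lss without day 14 (0.0575) and Fdps without day 1, 10 or 14 (up to 0.0754). Fry did not call the cholesterol list (adjusted p = 0.0848).

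Glycolysis and hypoxia genes had 10 fallen and 1 risen of 20 (10 and 1 adjusted over the list alone), with camera adjusted p = 0.0033, and adjusted p = 0.601 with an estimated correlation. Vegfa, an angiogenic growth factor, fell at -0.71 ± 0.103 and the hexokinase gene Hk2 at -0.70 ± 0.117, while the vasodilator peptide gene Adm rose at 1.01 ± 0.104. Inflammatory cytokines and proteases had 7 fallen and 1 risen of 14 (8 and 1 adjusted over the list alone), with camera adjusted p = 0.0152, and adjusted p = 0.601 with an estimated correlation. Il6 fell at -1.22 ± 0.169 and the prostaglandin synthase gene Ptgs2 at -1.19 ± 0.238, and the riser was Lcn2. Il6 and Ptgs2 were each detected on 3 of the 6 arrays, so background limits both slopes. Housekeeping reference genes had 8 fallen and 1 risen of 12 (9 and 1 adjusted over the list alone), with camera adjusted p = 0.00356, and adjusted p = 0.601 with an estimated correlation. Gapdh fell at -0.31 ± 0.0567 (adjusted p = 0.00931), the transferrin receptor gene Tfrc at -0.78 ± 0.165 and Pgk1 at -0.68 ± 0.0912, B2m rose at 0.39 ± 0.0855, and Actb did not pass at -0.13 ± 0.0497 (adjusted p = 0.0738; 0.0198 as the mean of its probes). These directions were the same under each scaling tried. Pgk1 was detected on 3 of the 6 arrays, so background limits its slope. The Actb signal lay at 91.2% or more of the highest signal on days 0 to 6, and Gapdh at 97.7% and 94.8% on days 0 and 1, so the size of these slopes is not resolved; a second probe of Actb gave -0.40 ± 0.0807. The glycolysis list lost its call without day 0 (adjusted p = 0.371), Ptgs2 (0.0520) and Tfrc (0.0703) without day 14, and B2m without day 10 or day 14 (up to 0.0640).

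Matrix and contractile genes with a call fell in all cases but 1. Tnc, the matrix glycoprotein tenascin C, fell at -1.04 ± 0.130, Fmod at -0.81 ± 0.165 and Loxl2, a collagen cross-linking enzyme, at -0.79 ± 0.114, while Dcn was the only riser among the collagen and extracellular matrix genes, at 0.69 ± 0.157. Of 28 measured members 12 fell and 1 rose (15 and 1 adjusted over the list alone), with camera adjusted p = 0.00346, and adjusted p = 0.601 with an estimated correlation. Smooth muscle and contractile genes had 8 fallen and 0 risen of 14, also adjusted over the list alone, with camera adjusted p = 0.00252, and adjusted p = 0.601 with an estimated correlation. Tagln, an actin-binding protein of smooth muscle, fell at -1.02 ± 0.170, the smooth muscle actin gene Actg2 at -0.98 ± 0.214 and Tpm1, a tropomyosin, at -0.59 ± 0.0898. The collagen list lost its call without day 0 (adjusted p = 0.0585), Fmod (0.0591) and Actg2 (0.0536) without day 14, Dcn without day 10 or day 14 (up to 0.0629), and fry did not call the smooth muscle list (0.0781).

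The remaining lists did not pass. Sox family transcription factors had 1 risen (Sox5) and 2 fallen (Sox11 and Sox6) of 6 measured (1 and 3 adjusted over the list alone; camera adjusted p = 0.818), with a median slope of 0.02 and a mean of -0.10. BMP and TGF-beta pathway genes had 9 risen and 7 fallen of 22, also adjusted over the list alone (camera adjusted p = 0.992; camera pointed up here but down with median scaling and in the signals as deposited, the median slope was 0.00 and the mean -0.05). Among them the receptor gene Bmpr1b fell at -0.96 ± 0.124 and Grem1, a BMP antagonist, at -0.69 ± 0.109. Bmpr1b was detected on 3 and Grem1 on 2 of the 6 arrays, so background limits both slopes. Wnt pathway genes had 3 risen and 3 fallen of 17, also adjusted over the list alone (camera adjusted p = 0.722; camera pointed down, the median slope was 0.04 and the mean -0.03), with Ccn4, a matricellular Wnt target, at -1.06 ± 0.0950. Notch and Hedgehog pathway genes had 2 risen and 1 fallen of 8 (2 and 1 adjusted over the list alone; 0.722), with Notch4 falling at -0.76 ± 0.145. Mesenchymal stromal cell markers had 3 risen and 4 fallen of 15, also adjusted over the list alone (0.804), with the hyaluronan receptor gene Cd44 falling at -0.70 ± 0.138 and the chemokine gene Cxcl12 rising at 0.89 ± 0.242. Another probe of Cxcl12 gave 0.20 ± 0.144, and the gene lost its call without day 6, 10 or 14 (adjusted p up to 0.110).

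Endothelial markers had 2 risen, Ramp2 and the receptor gene Flt1 at 1.25 ± 0.165, and 1 fallen of 5 (2 and 1 adjusted over the list alone; camera adjusted p = 0.381). Skeletal muscle markers had 1 fallen of 5, the sarcomeric actin gene Acta1 at -2.06 ± 0.299, and 0 risen (1 and 1 adjusted over the list alone; 0.545). Of the macrophage and leukocyte markers 2 were measured, too few for a list test: Cd14, a co-receptor for lipopolysaccharide, rose at 0.66 ± 0.128, also adjusted over the list alone, and Lyz2 did not pass at 0.09 (adjusted p = 0.738). Immediate early genes had 4 risen, among them Klf4 at 0.66 ± 0.0973 and Fos at 0.54 ± 0.0880, and 3 fallen of 19, also adjusted over the list alone (0.956; camera pointed up, the median slope was -0.11 and the mean -0.03). Circadian clock genes had 2 risen, Per1 at 0.44 ± 0.0792 and Per2 at 0.81 ± 0.211, and 1 fallen of 12, also adjusted over the list alone (0.381; adjusted p = 0.0205 and up without day 0). Per2 lost its call without day 6, 10 or 14 (up to 0.0819). Oxidative phosphorylation genes had 0 risen and 1 fallen of 21 (0 and 0 adjusted over the list alone; 0.115). Its member Atp5a1 did not pass, at -0.18 ± 0.0701, and a second probe of Atp5a1 pointed the other way, at 0.30 ± 0.0971. Antioxidant and detoxification genes had 5 risen, led by the retinal dehydrogenase gene Aldh1a1 at 1.34 ± 0.125 and Gstm1 at 1.03 ± 0.145, and 2 fallen of 20, also adjusted over the list alone (0.408). Secreted regulators of the bone and haematopoietic niche had 8 risen, led by Igfbp3, the stanniocalcin gene Stc2 at 1.201 ± 0.386 and Il34, a ligand of the macrophage colony-stimulating factor receptor, at 1.11 ± 0.193, and 2 fallen of 20, also adjusted over the list alone. Stc2 lost its call without day 1, 6, 10 or 14 (adjusted p up to 0.161). That list did not pass (0.109), but passed upwards without day 0 (0.0205) and among genes detected on all 6 arrays (0.0110). With fry, adjusted p was 0.0120 for the osteoblast transcription factors (down), 0.0115 for the chondrocyte genes (up), 0.0204 for the endothelial markers and the antioxidant genes (up) and 0.0353 for the skeletal muscle markers (down).

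Each later day was set against day 0 to describe how far the cells had moved from their undifferentiated state, with no test since each side is 1 array. On day 1 the chemokine gene Cxcl5 was 6.09-fold higher, Serpina3n 5.76-fold, Wnt2 5.38-fold, Hp 5.27-fold and Crct1 4.91-fold. Trib3 was 53.3-fold lower, Chac1 14.5-fold, the clock output gene Dbp 9.14-fold, Ddit3 8.42-fold and the folate enzyme gene Aldh1l2 7.98-fold; Trib3, Chac1 and Ddit3 are targets of the integrated stress response. On day 3 Hp was 48.8-fold higher, Cdkn1c 29.2-fold, Serpina3n 15.0-fold, Ifi205 14.6-fold and Tmem158 14.1-fold, and Trib3 was 38.2-fold lower, the collagen-like secreted protein gene C1qtnf3 26.9-fold, Timp3 13.8-fold, Acta1 13.5-fold and Chac1 13.2-fold. Serpina3n lay at 80.3% of the highest signal on day 3 and Timp3 at 69.0% on day 0, so the size and place of these folds are not resolved. Counting genes at least 2-fold apart, 323 were higher and 297 lower on day 1 (of 8133 detected on either array), and 615 higher and 368 lower on day 3 (of 8323). In the signals as deposited, without normalization, the median of all genes was 0.21 log2 units higher on day 1 than on day 0. There 82.2% of the genes at least 2-fold apart on day 1 were higher, against 52.1% after normalization, and the lower counts were 91 on day 1 and 188 on day 3.

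On day 6 Hp was 115.8-fold higher, Cdkn1c 96.3-fold, Apod 92.2-fold, Itgbl1 45.3-fold and Ramp1 37.7-fold, while Trib3 was 31.2-fold lower, Cxcl14 27.0-fold, Chac1 22.3-fold, Tgfbi 16.6-fold and Slc7a5 16.3-fold. On day 10 Apod was 166.8-fold higher, Cdkn1c 120.5-fold, Hp 119.4-fold, the alcohol dehydrogenase gene Adh1 65.9-fold and Pdk4 60.6-fold, while Cxcl14 was 57.1-fold lower, Uhrf1 46.6-fold, Chac1 38.6-fold, Plk1 37.5-fold and Prc1 34.7-fold. The 2-fold counts were 1141 higher and 936 lower on day 6 (of 8439) and 1358 higher and 1276 lower on day 10 (of 8464). Among genes detected on all 6 arrays, 694 were higher and 593 lower on day 6. On days 6, 10 and 14 the signals of Apod, Hp and Cdkn1c lay between 50.8% and 92.3% of the highest signal on the array, so the size and order of these folds are not resolved. A second probe of Hp gave 225.8-fold on day 6, 177.5-fold on day 10 and 380.4-fold on day 14.

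On day 14, the longest exposure, Apod was 148.6-fold higher than on day 0, Hp 109.5-fold, Cdkn1c 98.4-fold, Adh1 60.8-fold and Itgbl1 57.6-fold. Pdk4 was 49.6-fold, Ramp2 46.2-fold, Ndrg2 44.3-fold, Ifi205 43.7-fold and Selenop 43.1-fold higher. Cxcl14 was 53.2-fold lower, Uhrf1 45.6-fold, Plk1 38.3-fold, Prc1 35.0-fold and Chac1 34.3-fold, followed by Cdca3 (30.2-fold), the kinetochore motor gene Cenpe (28.5-fold), Trib3 (26.9-fold), Slc7a5 (25.2-fold) and Tpx2 (22.6-fold). Genes not detected on day 0 included Sult1a1, at least 210.6-fold higher on day 14, Scara5, a ferritin receptor, at least 181.1-fold, Lcn2 at least 109.0-fold, Plin4 at least 74.5-fold and Galnt15 at least 74.1-fold. Genes no longer detected on day 14 included Acta1, at least 97.5-fold lower, Birc5 at least 38.2-fold, Cdc20 at least 34.7-fold, Aurka at least 34.1-fold and Sox11 at least 32.7-fold. Sp7 was 8.92-fold lower, Alpl at least 5.79-fold lower, Col1a1 12.04-fold lower and Adipoq at least 8.73-fold higher. In the fold table deposited by the authors Sp7 was 5.71-fold, Alpl 4.16-fold, Col1a1 11.73-fold and Sox11 17.31-fold lower. The bounds for Alpl and Sox11 thus hold on the normalized scale and not on that of the authors. Col1a1 lay at 80.7% of the highest signal on day 0, so the size of its fold is not resolved. In total 1394 genes were at least 2-fold higher and 1216 lower (of 8668 detected on either array). Among genes detected on all 6 arrays 831 were higher.

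**Figure D2:**
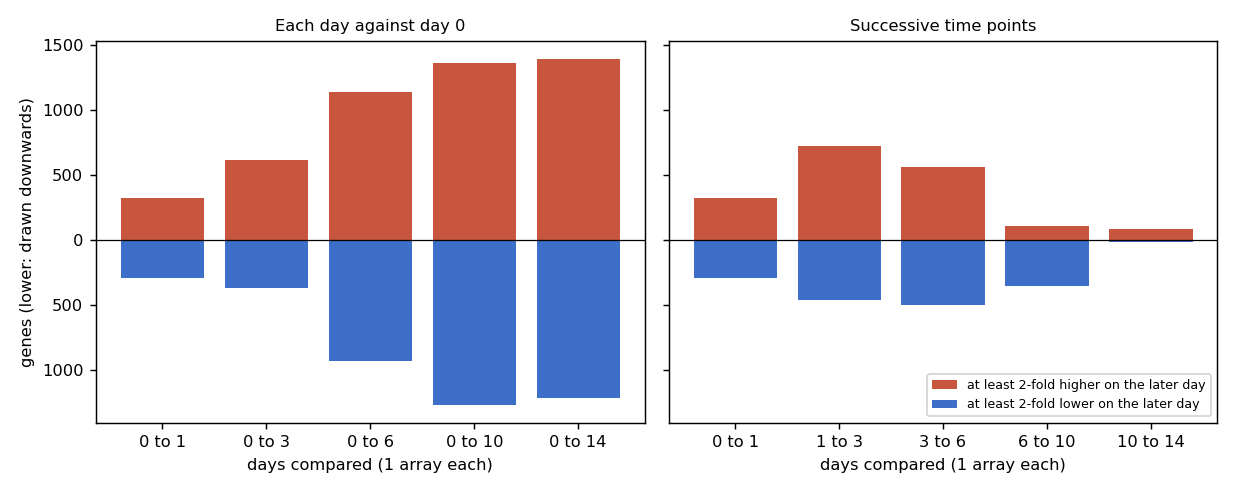
Number of genes at least 2-fold higher (upwards) or lower (downwards) on the later of the days compared, with 1 array per day, for each day against day 0 (left) and for successive time points (right). The counts against day 0 go from 323 higher and 297 lower on day 1 to 1394 and 1216 on day 14, and the step from day 10 to day 14 has 80 and 21.

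Successive time points describe when genes differed along the course. From day 1 to day 3 the angiotensin-converting enzyme gene Ace was 25.8-fold higher, the interferon-inducible Gbp3 16.52-fold and the claudin gene Cldn11 15.9-fold, and C1qtnf3 was 8.20-fold lower, Aldh1a3 7.46-fold and Cck 7.36-fold. From day 3 to day 6 Galnt15 was 42.1-fold higher, Lcn2 26.7-fold and Ramp1 18.7-fold, and Tgfbi was 13.9-fold lower, Tk1 12.6-fold and the chemokine gene Ccl9 10.3-fold. From day 6 to day 10 Gsta3 was 4.995-fold higher, Inmt 3.52-fold and Rab6b 3.40-fold, and the hyaluronan-degrading Cemip was 15.9-fold lower, Col1a1 8.66-fold and Actg2 8.60-fold. From day 10 to day 14 the neuropeptide gene Npy was 4.52-fold higher, Hpgd 4.08-fold and Car3 3.96-fold, and the phosphatase gene Dusp4 was 3.41-fold lower, Ankrd37 3.15-fold and Egr3 2.62-fold. The 2-fold counts were 719 higher and 467 lower from day 1 to day 3, 563 and 503 from day 3 to day 6, 107 and 354 from day 6 to day 10, and 80 and 21 from day 10 to day 14. The balance of the first 2 counts changed in the signals as deposited, with 383 higher and 501 lower from day 1 to day 3, and 354 and 376 from day 3 to day 6. With no background correction the last steps had 46 and 190, then 30 and 10, and the steps last from 1 to 4 days.

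Gene lists differed in their timing against day 0. Glucocorticoid-responsive genes had a median log2 difference of 1.25 on day 1, 2.60 on day 6 and 2.79 on day 14, at a percentile of 100 among 10000 random lists of matched size and expression on each day. Cell cycle genes had a median of 0.95 on day 1, when 11 of 27 were at least 2-fold higher, then -0.34 on day 3, -2.61 on day 6, -4.02 on day 10 (-3.38 with bounds) and -3.39 on day 14. Interferon response genes stood at -0.32 on day 1 and 2.39 on day 3 (1.62 with bounds), and remained at 1.98 (1.36 with bounds), 1.64 and 2.005 on days 6, 10 and 14. Only 7 of the 16 were detected on day 1, and with the others at their bounds 13 of 16 were at least 2-fold higher on day 3 than on day 1. Complement genes had medians of -0.62, 1.497, 3.11, 3.11 and 3.28 at days 1, 3, 6, 10 and 14. Cholesterol biosynthesis genes were at 0.13 and 0.37 on days 1 and 3, then at -1.30 on day 6, -2.46 on day 10 (-2.01 with bounds) and -1.66 on day 14. Endoplasmic reticulum stress and amino acid response genes were at -0.81 from day 1 and at -1.60 on day 14, and circadian clock genes were lowest on day 1, at -0.82. Adipocyte genes went from -0.10 on day 1 to 1.30 on day 14, whereas the osteoblast and mineralised matrix genes were at 0.02 on day 1, 0.47 on day 3 and 0.07 on day 14; the day 1 values changed sign for the adipocyte genes in the signals as deposited and for the osteoblast matrix genes with median scaling. With members detected on only 1 of both arrays set at their bounds, and members without a fold or bound left out, the day 14 medians were -3.47 for 26 cell cycle, 2.60 for 22 glucocorticoid-responsive, 1.66 for 14 interferon response, 1.86 for 17 adipocyte and -1.72 for 14 inflammatory genes. The same members had medians of -3.55, 2.79, 2.16, 1.86 and -2.54 without bounds, so the higher adipocyte value comes from the 2 members left out.

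**Figure D3:**
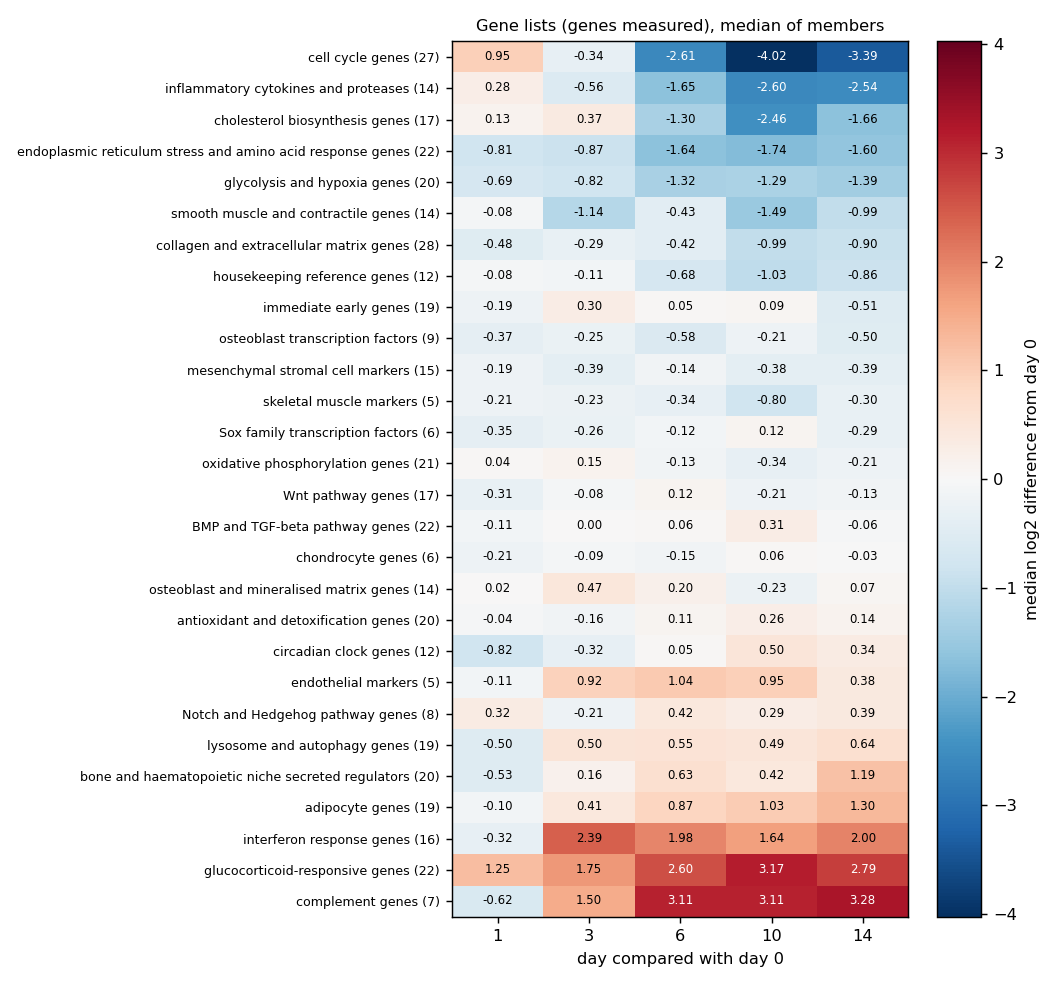
Median log2 difference from day 0 of the measured members of 28 gene lists (vertical, number measured in brackets) at days 1, 3, 6, 10 and 14 (horizontal), with 1 array per day. Red stands for higher and blue for lower than day 0. Cell cycle genes go from 0.95 on day 1 to -3.39 on day 14 and complement genes from -0.62 to 3.28.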

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

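The test of other array orders was chosen before the data were examined, and every other test in this part was chosen after the result was seen.

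Outside the gene-level comparisons, 3312 probes were detected on at least 1 array but carry no gene name in the table used here, and none of the comparisons uses them. They are singled out because they hold signal above background in data on which the report does not draw. Along the time trend 610 of them rose and 601 fell (limma, adjusted p of 0.05 over these probes), and 584 were at least 2-fold higher and 535 at least 2-fold lower on day 14 than on day 0. The largest difference between arrays that both detected the probe was 72.0-fold higher on day 14. Of these probes 185 lie outside the series matrix, and no biological explanation was tested for them.

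The first pattern is the time trend itself, with 3220 genes passing in the real order of the arrays. Among 100 orders of the 6 arrays, the real one included, 1 gave as many genes, the real order. This argues against a chance assignment of the time points, at a resolution of 1 in 100. The highest of the other orders, with days 0 and 1 exchanged and days 6 and 14 exchanged, gave 2632 genes, and the median of the others was 0. The draw therefore does not exclude an exchange of some of the time points. A steady drift in culture conditions, unrelated to the medium, would order the arrays in the same way and stays open.

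The second pattern concerns Sp7, Alpl and Col1a1, all tied to the osteoblast lineage, which fell over the course in osteogenic medium. Over the same days 10 of 19 adipocyte and 15 of 22 glucocorticoid-responsive genes rose (camera adjusted p = 0.601 for both lists with an estimated correlation). On genes detected on all 6 arrays the adipocyte list had a camera adjusted p of 0.366, but that filter drops risers such as Plin4 and Adipoq. The pattern covers only part of the osteoblast programme: Omd, Mgp and Smpd3 rose at 1.51, 1.33 and 1.13, and the mineralised matrix list did not pass (camera adjusted p = 0.956). Alpl lost its call without day 10 or 14 (limma adjusted p up to 0.0717) and Col1a1 without day 1, 10 or 14 (up to 0.136). The falls were not early ones: on day 1 Sp7 and Alpl stood at 11.60 and 9.64, above 10.38 and 9.17 on day 0. The normalization is argued against as the source of the 3 falls, since in the signals as deposited the smallest difference between day 14 and day 0 was -2.001 on the log2 scale (Alpl), with -2.42 for Sp7 and -3.53 for Col1a1. Time points labelled in reverse are argued against too, because the medium holds dexamethasone and 100% of the 22 measured glucocorticoid-responsive genes were higher on day 14 than on day 0, with a list median of 1.25 already on day 1. An effect of time in culture apart from the medium cannot be told apart from an effect of the medium, since 0 arrays come from a parallel culture without it.

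The third pattern is the step in interferon response genes between day 1 and day 3, with a median of 2.46 log2 units, or 1.75 with 13 of 16 members at least 2-fold higher when the 9 not detected on day 1 are set at their bounds. A single deviating array on day 3 is argued against, because the lowest median of days 6, 10 and 14 against day 1 was still 1.96 (1.499 with bounds). The normalization is argued against as the source, because the step was 1.38 in the signals as deposited. A growing share of leukocytes cannot be told apart from a response of the stem cells, since only 2 leukocyte markers were measured: Lyz2 was not detected on day 1 or day 3, and Cd14 differed by 0.47 log2 units. What set off the step, whether medium, cell density or handling of the cultures, stays open and could not be tested with 1 array per time point.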

How the results depend on the processing

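All settings in this part were chosen before the data were examined. With 1 array per time point the single days have no spread, so a value without a test counts as changed when it differs as printed. Of the 3220 calls, 3180 were kept in the same direction without background correction, 3047 with median scaling, 2621 in the signals as deposited, 3196 with an offset of 50, 2320 with the day as a number and 2956 with its rank. Called in the opposite direction were 0 in each of these settings and 2 with the mean of all probes. Fewer calls were kept when a late time point was left out: 1019 without day 14, 1403 without day 10 and 2170 without day 6. There too 0 were called in the opposite direction. Of 142 named genes with a call, 88 passed without each single time point and 0 changed direction. Of 13 called lists, 11 passed without each time point, and 0 passed with an estimated correlation (0 up and 0 down). No paired analysis was possible because the labels give no replicate shared between time points. The chip as a block and bead standard errors were not run, since neither is given in the files used here, and detection on all 6 arrays gives no value for Sox11. The cause was not tested for any change given here, except where fewer genes tested or another threshold explains it by construction.

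The trend counts lay between 590 and 1659 risen and between 432 and 1587 fallen as each time point was left out, lowest without day 14. With a linear and a quadratic term they were 973 and 859, and with days 1 to 14 as 1 group against day 0 they were 0 and 0 (limma, 535 at an unadjusted p under 0.05), where Sox11 gave -3.38 without passing. That last contrast sets 1 array against 5 and counts the trend among them as error, so it says nothing about stability. The difference of Sox11 between day 14 and day 0, -5.13 in the report, was -4.11 without background correction, -5.07 with median scaling, -4.02 in the signals as deposited, -4.70 with an offset of 50 and -4.39 as the mean of its probes.

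Counts of genes at least 2-fold apart, higher then lower, changed by over 1.5 times as follows. Without background correction they were 181 and 153 on day 1, 239 lower on day 3, 302 lower from day 1 to day 3, 46 and 190 from day 6 to day 10, and 30 and 10 from day 10 to day 14. In the signals as deposited the lower counts were 91, 188 and 835 on days 1, 3 and 10, 383 and 501 from day 1 to 3 and 354 and 376 from day 3 to 6, with the balance reversed, and the last steps 62 and 157, then 26 and 13. An offset of 50 gave 13 lower in the last step. Among genes detected on all 6 arrays, where fewer genes are counted, they were 163 and 168 on day 1, 368 and 236 on day 3, 694 and 593 on day 6, 839 higher on day 10 and 831 higher on day 14. The steps there had 443 and 267, 294 and 246, 36 and 189, and 32 and 13. A 1.5-fold threshold gave 967 and 920, 1336 and 1055, 1963 and 1881, 2236 and 2219, and 2289 and 2148 on days 1, 3, 6, 10 and 14. A 3-fold threshold gave 78 and 93, 260 and 128, 593 and 390, 710 and 635, and 737 and 578. In the fold table deposited by the authors the counts were 179 and 151 on day 1 and 403 and 241 on day 3.

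List directions reversed only for lists without a call, given here as camera or fry adjusted p. BMP and TGF-beta pathway genes pointed down with median scaling (0.959), in the signals as deposited (0.914), with the mean of probes (0.897) and with fry (0.459). Without single time points they ranged from 0.844 to 0.967, pointing down without day 3, 6 or 10. Osteoblast and mineralised matrix genes pointed up with no detection filter (0.945) and with fry (0.945), and ranged from 0.696 to 0.972 without single time points, up without day 10 or 14. On genes detected on all 6 arrays, Notch and Hedgehog genes pointed down (0.821) and Sox family genes up (0.792). Sox family genes ranged from 0.720 to 0.947 without single time points, and stromal cell markers from 0.619 to 0.947, both up without day 0. Immediate early genes pointed down with the day as a number (0.865) and its rank (0.962), and ranged from 0.619 to 0.987 without single time points, down without day 1, 3 or 10.

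Slopes reversed only for named genes without a call in the report. Atp5a1 gave 0.059 as the mean of its probes. As days 1 to 14 against day 0, Ankrd37 gave -0.94, Dbp -1.50, Egr3 0.39, Lyz2 -0.33 and Tnnt1 0.0059. Without single time points the ranges were -0.13 to 0.59 for Ankrd37 (negative without day 1 or 10), -0.10 to 0.95 for Dbp (negative without day 1), -0.39 to 0.53 for Ddit3 and -1.08 to 0.52 for Trib3 (both positive without day 0). Without day 0 Ddit3 passed upwards (adjusted p = 0.00994) and Trib3 did not (0.0708), so their negative slopes rest on the day 0 array. They were -0.41 to 0.027 for Dusp4 and -0.50 to 0.12 for Egr3 (both positive without day 14), and -0.0042 to 0.33 for Lyz2 (negative without day 1). Signal over background limits the smallest levels: folds of dim genes shrink when no background is subtracted, as for Sox11.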

Other observations

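The gene families in this part were chosen, and their tests run, after the data were seen. Aminoacyl-tRNA synthetases of the cytosol, which charge tRNAs with amino acids, fell along the time trend, with 13 fallen and 0 risen of 15 measured. Aars fell at -0.66 ± 0.0741 and Cars at -0.63 ± 0.0723 (log2 per unit of log2(day + 1), ± SE), and both passed without each single time point. The family had a camera adjusted p of 2.2e-06 over 7 families, and adjusted p = 0.298 with an estimated correlation. Proteasome subunits had 12 fallen and 1 risen of 36, the immunoproteasome subunit Psmb9 (camera adjusted p = 8.2e-05, and adjusted p = 0.540 with an estimated correlation). Chaperonin subunits, which fold actin and tubulin, had 5 fallen and 0 risen of 8 (adjusted p = 0.00563, and adjusted p = 0.540 with an estimated correlation). Mitochondrial ribosomal proteins had 11 fallen and 1 risen of 67 (camera adjusted p = 0.00394, and adjusted p = 0.600 with an estimated correlation). Their share of fallen genes was no larger than among all tested genes, where 1572 of 8881 fell. The median slope of this family was -0.10.

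Glutathione S-transferases, which conjugate glutathione to reactive compounds, had 7 risen and 0 fallen of 13, with Gstm6 at 1.06 ± 0.129 and Gstm1 at 1.03 ± 0.145 (camera adjusted p = 0.00667, and adjusted p = 0.540 with an estimated correlation). Cytosolic ribosomal proteins, with 5 fallen and 0 risen of 47, and integrins, with 1 risen and 2 fallen of 9, did not pass (camera adjusted p = 0.433 for each). The median slope of each of the 7 families had the same sign with median scaling and in the signals as deposited.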
